A study of Mus musculus with 24 samples.

How the data were processed

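RNA of the left ventricle was measured in 24 male mice of a mixed genetic background, with 1 Illumina mouse array per heart. The labels give 3 groups: 11 wild-type controls (WT) and 13 mice with a cardiac-specific knockout (KO) of EP4, a prostaglandin E receptor encoded by Ptger4, of which 6 are labelled low and 7 high ejection fraction (EF). Per the labels, RNA came from a Qiagen kit for fibrous tissue with a DNase step, was checked on an Agilent Bioanalyser and was labelled with biotin by an Illumina kit, and the data passed through BeadStudio (version not given) and R 2.8.0. Whether the WT mice carried the recombinase is not given in the sources used here.

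The authors deposited 3 kinds of values for 45281 probes. The deposited unnormalized table gives fluorescence intensity on a linear scale, with no detection p-values or negative controls, and its background setting is not stated. The deposited normalized table is on a log2 scale at its bright end, compressed at its dim end as a variance-stabilizing transformation gives, and holds 1 distribution of values in each column, with a column median of 8.09. The R package and the transformation behind it are not given in the sources used here. The authors' summary table holds log2 group means, which match the group means of that normalized table. Beside them the authors' summary table holds group standard deviations, whose unit is other than a level and which match the same table. It also holds the authors' p-value for each probe, whose test is not stated in the header. These p-values matched limma's moderated F test over the 3 groups on the authors' values within 0.0021 log10 units.

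The unnormalized intensities were background-corrected with normexp (offset 50), log2-transformed and quantile-normalized in limma 3.58.1 under R 4.3.3 with the data.table package (1.17.8). Normalized values reach the same top on every array, so changes of the brightest probes are compressed. A probe was kept if its value exceeded its array's median in at least 6 arrays, the size of the smallest group, which left 25425 probes. The array median was 6.77, and 52.7% of kept probes had a mean under 8 on the log2 scale. Arrays give no read depth, and their number limits the precision. Gene symbols came from the platform's annotation for 34885 probes, 2735 more were named through the authors' table, and 7661 stayed unnamed. Of 28339 probes named by both sources, 98.9% had the same symbol. Gene positions came from a GRCm38 annotation and served for the order of genes around Ptger4; the place of each probe within its gene was not used here.

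Groups were compared with limma (lmFit and eBayes, two-sided) in 1 fit with 3 group means, for KO low EF against WT, KO high EF against WT, KO low EF against KO high EF, and the mean of both KO groups against WT. Slopes on EF, per 10 points, were fitted within KO and within WT, and their difference was tested as an interaction. P-values were adjusted by Benjamini-Hochberg over all kept probes, with a threshold of 0.05. Values are log2 differences ± standard error unless an SD is named. Simulated data with 200 changed probes were used to test the procedure, and it recovered 181 of them for KO low EF against WT, with 15 false calls.

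Before the data were examined, 40 gene lists were fixed: cardiac stress and contraction, ion handling, matrix, energy metabolism, signalling, stress responses, immunity, and markers of other cell types. 926 of their 935 members were on the array. Each list was tested against all other genes with limma's camera (preset correlation 0.01, 1 probe per gene, the brightest kept one) and adjusted over the lists. Camera with an estimated correlation and fry served as alternatives. Fry tests a list against no change, so ranges of a list's adjusted p span the camera alternatives only. The named genes were also set by rule beforehand: Ptger4 and 13 genes of heart failure, and the 10 largest rises and 10 largest falls past the threshold among probes with a gene symbol that lay above the array median on every array of the higher group, 1 probe per gene, the one with the smallest p. Another probe of a gene can show a larger change. Predicted and clone names were counted instead of named. Some genes that the rule takes are not reported here. Counts of named genes include them, and the tests for deviating arrays were rerun without them after the first results were seen. For the EF slopes the rule took 5 genes each way, above the array median on at least 6 arrays. Of each list described, up to 4 members with the smallest p were named, on the list's own probe. For the WT slopes, where no probe passed, the rule took the 5 genes with the smallest p. EF and age were compared by permutation tests, exact where a group had under 10 hearts.

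The array labels have a prefix with a letter from A to F, which was read as the chip and the position on it, giving 4 chips of 6 positions. The values include those with the chip as a fixed block and within each chip that holds both groups. Alternatives set beforehand changed the background correction, the normalization between arrays, the source of the values, the filter, the variance model, array weights, age, chip, replicate block, samples in the fit and threshold, and left out each array in turn. The planned filter on detection p-values could not be run, and the planned normexp with quantile normalization became the procedure itself. Alternatives added after the array of KO high EF replicate 11 was seen to stand apart left out that array, alone, with WT replicate 1 next to it on the chip, with median scaling, with the chip as a block or with an estimated correlation. Others kept probes above the median in every array but that 1, or limited the lists to less bright probes. Median scaling of the lists with all arrays was also added then. No array was left out of the main values. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.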

Results

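Gene expression was measured in the left ventricle of 24 male mice from a series described as a mouse model of dilated cardiomyopathy. There were 11 wild-type controls (WT), 6 cardiac-specific EP4 knockout (KO) hearts with low ejection fraction (EF) and 7 KO hearts with high EF, with 1 array per heart. The median raw intensity per array ran from 106 to 155, and 25425 of 45281 probes were kept for testing. The lowest median was that of KO high EF replicate 11. On normalized values, its median correlation with the other arrays was 0.778, against 0.968 to 0.986 for the 23 others. The arrays lay on 4 chips. Chip 1 held 4 WT, 1 KO low EF and 1 KO high EF heart, chip 2 held 3, 2 and 1, chip 3 held 1, 3 and 2, and chip 4 held 3 WT, 3 KO high EF and no KO low EF heart.

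EF was 79.5 ± 4.66% (SD, n = 11) in WT, 56.8 ± 10.4% (SD, n = 7) in KO high EF and 24.8 ± 6.96% (SD, n = 6) in KO low EF hearts. All KO hearts together had 42.0 ± 18.7% (SD, n = 13), which was -37.5 points from WT (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The 2 KO groups were formed by EF, so EF was not tested between them. Mean age was 31.5 weeks in WT, 30.8 in KO low EF and 30.6 in KO high EF mice. Age did not differ past the threshold between all KO and WT (permutation p = 0.355), KO low EF and WT (exact permutation p = 0.548), KO high EF and WT (exact permutation p = 0.433) or the KO groups (exact permutation p = 0.824). With KO high EF replicate 11 left out, the first principal component held 39.6% of the variance. WT hearts scored from -37.8 to -18.9 on it, KO high EF hearts from 3.9 to 25 and KO low EF hearts from 31.1 to 38.5.

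**Figure D1:**
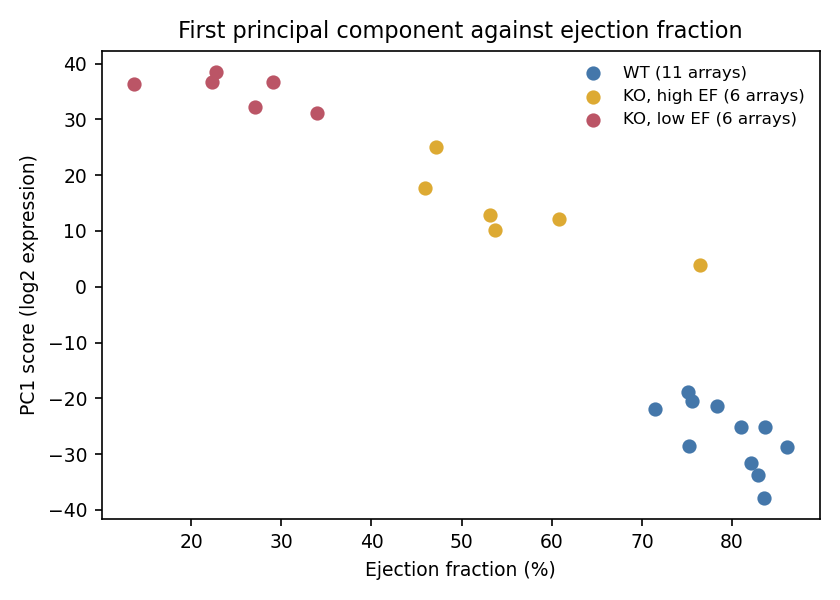
Each point is 1 heart, with EF in percent on the horizontal axis and the score on the first principal component of the kept probes on the vertical axis, coloured by group, with KO high EF replicate 11 left out. The groups do not overlap on the vertical axis: WT lies from -37.8 to -18.9, KO high EF from 3.9 to 25 and KO low EF from 31.1 to 38.5.

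Ptger4, the targeted gene, lies on chromosome 15 (5233399 to 5244187, GRCm38). Its 1 kept probe measured 6.90 ± 0.13 (SD, n = 11) in WT on the log2 scale, close to the array median of 6.77. The difference from WT was -0.04 ± 0.14 in KO low EF (n = 6, adjusted p = 0.901), 0.20 ± 0.13 in KO high EF (n = 7, adjusted p = 0.338) and 0.08 ± 0.11 over all KO hearts (adjusted p = 0.673). Without KO high EF replicate 11 the last 2 were 0.055 ± 0.097 and 0.007 ± 0.080. A further Ptger4 probe stayed at or below 6.67 on every array. The place of these probes relative to the deleted part of the gene is not known here, and cells other than cardiomyocytes would keep the gene in a cardiac-specific knockout. The labels call all mice male: the brightest probes of the Y-linked genes Ddx3y (11.55 to 12.59) and Eif2s3y (10.08 to 11.43) were bright on every array, and no Xist probe exceeded 7.36.

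The comparison of KO low EF with WT asks how hearts with strongly reduced EF differ from controls. Matrix and stress genes had the largest rises. Comp, a cartilage and tendon matrix protein, rose by 4.39 ± 0.65 on the log2 scale (20.9-fold, 6 against 11 hearts). WT hearts were spread widely for Comp, with 7 at 7.08 to 7.72 and 4 at 9.95 to 10.53, so this fold depends on the controls. The other kept Comp probe rose by less (2.98 ± 0.44). Nmrk2, a nicotinamide riboside kinase, rose 19.3-fold (4.27 ± 0.27), and Timp1, an inhibitor of matrix metalloproteinases, 16.4-fold (4.03 ± 0.38). Lox, which crosslinks collagen and elastin, rose 12.0-fold (3.59 ± 0.47), and Gdf15, a secreted stress-induced factor, 11.9-fold (3.57 ± 0.26). The microfibril genes Mfap5 (9.41-fold, 3.23 ± 0.19) and Mfap4 (9.15-fold, 3.19 ± 0.18), Serpina3n, a serine protease inhibitor (8.70-fold, 3.12 ± 0.75), and Lgals3, or galectin-3 (8.57-fold, 3.10 ± 0.27), were also among the 10 largest rises.

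Among the 10 largest falls, Ces1d, a carboxylesterase, was 7.11-fold lower (-2.83 ± 0.24). Amy2a5, a pancreatic-type amylase, was 6.11-fold lower (-2.61 ± 0.16), but its other kept probe measured only -0.63 ± 0.14. Ttll1, a tubulin polyglutamylase subunit, was 5.58-fold lower (-2.48 ± 0.14). Kcnv2, a modifier subunit of potassium channels, was 5.08-fold lower, Acot1, an acyl-CoA thioesterase, 4.96-fold lower on the probe with the smallest p (-2.31 ± 0.17; -2.85 ± 0.23 on its other kept probe), and Fbp2, the muscle fructose bisphosphatase, 4.66-fold lower (-2.22 ± 0.42). Ky, a muscle gene whose loss gives kyphoscoliosis in mice, was 4.30-fold lower, Immp2l, a mitochondrial inner membrane peptidase subunit, 4.28-fold lower (-2.10 ± 0.08), and Gpr22, an orphan receptor, 4.21-fold lower. Adjusted p over the 20 genes taken by the rule ran from 5.91e-15 (Immp2l) to 0.00258 (Serpina3n).

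Of the genes of heart failure fixed beforehand, the natriuretic peptides Nppa (1.25 ± 0.24, 2.37-fold) and Nppb (1.32 ± 0.18, 2.50-fold) rose, as did Myh7, the slow myosin heavy chain (1.97 ± 0.28, 3.92-fold), Acta1, skeletal alpha-actin (1.00 ± 0.21), and Ankrd1 (0.42 ± 0.07). Ccn2, or connective tissue growth factor (2.43 ± 0.20, 5.38-fold), the collagens Col1a1 (2.33 ± 0.14, 5.03-fold) and Col3a1 (2.13 ± 0.46, 4.38-fold) and Postn, or periostin (0.88 ± 0.15), rose too. Pln, the inhibitor of the calcium pump Atp2a2, fell by 0.72 ± 0.09. Myh6, the fast myosin heavy chain, measured -0.04 ± 0.04 (adjusted p = 0.657) and Atp2a2 0.05 ± 0.05 (adjusted p = 0.615) on probes near the top of the scale. A less bright Myh6 probe fell by 1.01 ± 0.11 (2.01-fold lower, adjusted p = 1.28e-07) and a less bright Atp2a2 probe by 0.41 ± 0.08 (adjusted p = 0.000297). Nppa, Nppb, Acta1 and Ankrd1 are also near the top, as is Ccn2 in KO low EF hearts (mean 15.74), so their folds may be too small.

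Among the lists, 41 of 47 measured genes of extracellular matrix and fibrosis rose and none fell (41 also when adjusted over the list alone; adjusted camera p = 2.12e-27, 0.00114 with an estimated correlation). Their median was 1.59, with 1.43 to 1.59 within chips and 1.49 with the chip as a block, and examples were Fbn1 (2.25 ± 0.12), Mfap4, Mfap5 and Col1a1. Of 18 fetal and stress genes of the ventricle, 14 rose and none fell (15 adjusted over the list alone), among them Nmrk2, Gdf15, Ccn2 and Uck2 (1.98 ± 0.18). The median was 1.41, within chips 0.91 to 1.42 and with the chip as a block 1.14. The list's adjusted p was 6.8e-10, and 0.0146 with an estimated correlation. Macrophage markers rose in 21 of 22 genes (21 adjusted over the list alone), with C1qb at 1.38 ± 0.11, Mrc1 at 1.09 ± 0.10 and Fcgr3 at 1.25 ± 0.12. The median was 1.11, within chips 0.86 to 1.07 and with the chip as a block 1.01. Fibroblast markers rose in 14 of 20 genes and fell in 1 (15 and 1 adjusted over the list alone), with Pi16 at 2.08 ± 0.16 and Cd248 at 1.32 ± 0.10. The median was 0.55, within chips 0.39 to 0.75 and with the chip as a block 0.55. Complement and coagulation genes rose in 10 of 20 (11 adjusted over the list alone), led by C1qb, C4b (1.82 ± 0.17) and C1qc (1.17 ± 0.12). This list shares C1qa, C1qb and C1qc with the macrophage list, so the rises of these lists overlap. The median was 0.70, within chips 0.61 to 0.83 and with the chip as a block 0.59. With an estimated correlation the adjusted p was 0.00484 for macrophage, 0.0266 for fibroblast and 0.0283 for complement genes. With KO high EF replicate 11 also left out it was 0.0195, 0.0601 and 0.0412, the highest of 9 camera alternatives each, so fibroblast markers lost the threshold there. The lowest were 2.51e-17, 6.85e-09 and 4.63e-07.

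Lists of fatty acid and mitochondrial energy metabolism fell. Fatty acid oxidation and uptake genes fell in 26 of 34 and rose in none (27 lower adjusted over the list alone), including Acsl1, which activates long-chain fatty acids (-1.17 ± 0.09), Plin5 of lipid droplets (-0.90 ± 0.07) and Hadhb of the trifunctional protein (-0.67 ± 0.06). The median was -0.79, within chips -0.80 to -0.70 and with the chip as a block -0.83. Genes of the tricarboxylic acid cycle and pyruvate dehydrogenase fell in 16 of 22 and rose in 1 (17 and 1 adjusted over the list alone), such as Idh3a (-0.63 ± 0.06), Mdh2 (-0.69 ± 0.07) and Dlat (-0.88 ± 0.10). The median was -0.59, within chips -0.58 to -0.51 and with the chip as a block -0.59. Nuclear subunits of oxidative phosphorylation fell in 44 of 72 (47 adjusted over the list alone), such as Sdhd (-0.73 ± 0.08) and Ndufb11 (-0.76 ± 0.09). This list shares Sdha, Sdhb, Sdhc and Sdhd with the tricarboxylic acid cycle list. The median was -0.32, within chips -0.37 to -0.27 and with the chip as a block -0.37. Ion channel and gap junction genes fell in 11 of 24 and rose in 1, the same adjusted over the list alone (median -0.42; within chips -0.45 to -0.26, chip-blocked -0.33), with Kcnj3 at -1.24 ± 0.10 and Kcnip2 at -1.03 ± 0.13. With an estimated correlation the adjusted p was 0.00114, 0.00114, 0.00125 and 0.0234 for these 4 lists in turn.

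The remaining 4 lists past the threshold did not keep it with an estimated correlation. Calcium handling genes fell in 6 of 18 and rose in 1, also adjusted over the list alone (median -0.33; adjusted p = 0.0101, and 0.0508 with an estimated correlation; within chips -0.41 to -0.20, chip-blocked -0.34), with Hrc, which binds calcium in the sarcoplasmic reticulum, at -1.35 ± 0.11 and Camk2b at -1.22 ± 0.14. Cell cycle genes rose in 15 of 29, also adjusted over the list alone (median 0.30; adjusted p = 0.00123, and 0.355 with an estimated correlation; within chips 0.15 to 0.39, chip-blocked 0.30), such as Tyms (0.85 ± 0.14) and Mcm6 (0.79 ± 0.16). Genes of STAT3 and the interleukin 6 family rose in 8 of 20 and fell in 2 (9 and 2 adjusted over the list alone; median 0.43; adjusted p = 0.0425, 0.0757 with an estimated correlation and 0.0683 with the chip as a block; within chips 0.23 to 0.63), with Lbp at 1.79 ± 0.16 and Lifr, a receptor subunit of that family, at -0.93 ± 0.10. Ribosomal protein genes rose in 12 of 45 (14 adjusted over the list alone; median 0.17, within chips 0.12 to 0.18), with Rpl3 at 0.96 ± 0.11. The adjusted p of 7.16e-05 became 0.0757 with an estimated correlation and 0.299 with arrays scaled to a common median. For the first 3 of these lists the highest p of 9 camera alternatives, with an estimated correlation and without KO high EF replicate 11, was 0.077, 0.423 and 0.128, and the lowest were 0.000381, 0.000329 and 0.00326. For ribosomal genes the range was 8.5e-06 to 0.299. Sarcomere genes as a list did not pass (3 of 23 higher and 4 lower, 3 and 5 adjusted over the list alone, median -0.03, adjusted p = 0.674), although 15 of the 23 are near the top of the scale. Median scaling without KO high EF replicate 11 gave -0.11 (adjusted p = 0.0275, the lowest of 9 camera alternatives, with 0.740 as the highest).

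In this comparison limma called 6205 probes, 3069 higher and 3136 lower, of which 441 rose and 266 fell at least 2-fold, and 473 carried no usable gene name. The even balance was lost with median scaling, which gave 3026 higher and 1537 lower, and 4497 and 2341 without KO high EF replicate 11. Of the called probes 97.6% had the same sign within each of the 3 chips holding both groups, against 53.2% of all kept probes. In each comparison, called probes and named genes were chosen on these same arrays, which favours a shared sign. The count was 5462 with the chip as a block and 8502 without KO high EF replicate 11, with 6198 probes called both ways. All 30 named genes past the threshold kept their sign within each chip and stayed past it with the chip as a block. Of the further probes of these genes, 13 passed in the named direction. A Nmrk2 probe moved against the named one (-0.62 ± 0.07, adjusted p = 5.85e-07), and a Ttll1 probe measured 0.05 ± 0.08 (adjusted p = 0.775), while another probe of each agreed (3.97 ± 0.54 and -2.27 ± 0.15).

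The comparison of KO high EF with WT asks what differs where EF is less reduced. Timp1 rose 12.1-fold (3.59 ± 0.37, 7 against 11 hearts), Gdf15 7.95-fold (2.99 ± 0.25) and Nmrk2 7.76-fold (2.96 ± 0.26). Ccl8, a chemokine for monocytes, rose 5.62-fold (2.49 ± 0.24), Mfap5 5.26-fold, Comp, with its wide spread in WT, 5.02-fold (2.33 ± 0.62), Rcan1, a regulator of calcineurin, 4.79-fold (2.26 ± 0.30), and Mfap4 4.56-fold. Tnc, or tenascin C, rose by 2.29 ± 0.30 from WT values near the array median (6.49 to 7.16), so its fold may be too small. The rule could not take Lox or Serpina3n here, as KO high EF replicate 11 lay below the array median for both (5.9 and 6.27). In the other KO high EF hearts Lox measured 9.46 to 10.95, against 6.94 to 8.73 in WT. Serpina3n measured 13.36 to 14.44 there, against 10.4 to 12.16 in WT. Amy2a5 was 3.79-fold lower (-1.92 ± 0.15), Immp2l 3.66-fold lower (-1.87 ± 0.08), Ttll1 3.06-fold lower, Kcnv2 2.89-fold lower and Amy1, the salivary-type amylase, 2.68-fold lower. The other kept Amy2a5 probe measured only -0.61 ± 0.14.

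A further 4 large falls rested in size on KO high EF replicate 11: Fah, of tyrosine breakdown, measured -1.88 ± 0.49 and -1.18 ± 0.21 without that array. Likewise, Slc40a1, the iron exporter ferroportin, measured -1.70 ± 0.49 and -1.08 ± 0.30, Fbp2 -1.66 ± 0.40 and -1.09 ± 0.17, and Dcakd -1.53 ± 0.52 and -0.72 ± 0.09. All 4 passed both ways (adjusted p without it 0.0002, 0.0118, 4.44e-05 and 1.91e-06), but Dcakd (adjusted p = 0.0499 with all arrays) passed under only 16 of 41 alternatives. With the chip as a block, Slc40a1 (adjusted p = 0.0513, 0.00364 to 0.149 over 41 alternatives) and Dcakd (adjusted p = 0.0929, 1.68e-06 to 0.134) no longer passed, while the other 28 named genes past the threshold did, and all 30 kept their sign within each of 4 chips. Of the genes fixed beforehand, Nppa (1.27 ± 0.23), Nppb (2.29-fold), Col1a1 (1.75 ± 0.14, 3.37-fold), Ccn2 (1.75 ± 0.19), Myh7 (0.94 ± 0.27), Acta1 (0.86 ± 0.20), Postn (0.53 ± 0.14) and Ankrd1 rose and Pln fell by 0.35 ± 0.09. Col3a1 rose by 1.31 ± 0.44, and by 1.96 ± 0.16 without replicate 11, and it passed under 15 of 41 alternatives (adjusted p from 2.39e-09 to 0.315). The other kept Col3a1 probe rose by 1.20 ± 0.17 with all arrays (adjusted p = 1.72e-05) and by 1.19 ± 0.17 without replicate 11. Myh6 fell by 0.41 ± 0.10 on its less bright probe (adjusted p = 0.00743) and measured -0.01 ± 0.04 on the brighter one (adjusted p = 0.937). Atp2a2 fell by 0.31 ± 0.08 on its less bright probe (adjusted p = 0.0053) and measured -0.03 ± 0.05 on the named one (adjusted p = 0.705).

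Matrix genes rose in 33 of 47 (33 adjusted over the list alone), with Fbn1 at 1.55 ± 0.11. The median was 1.06, within chips 0.84 to 1.52 and with the chip as a block 1.05. Macrophage markers rose in 18 of 22 (20 adjusted over the list alone), with Mrc1 at 1.10 ± 0.09. The median was 0.98, within chips 0.92 to 1.06 and with the chip as a block 0.95. Fetal and stress genes rose in 13 of 18 (14 adjusted over the list alone), with Uck2 at 1.40 ± 0.17. The median was 0.82, within chips 0.62 to 1.15 and with the chip as a block 0.89. Fibroblast markers rose in 14 of 20 (15 higher and 1 lower adjusted over the list alone). The median was 0.49, within chips 0.34 to 0.73 and with the chip as a block 0.54. Complement genes rose in 11 of 20 (12 adjusted over the list alone), with F13a1 at 1.03 ± 0.11. The median was 0.49, within chips 0.58 to 0.86 and with the chip as a block 0.48. Fatty acid oxidation genes fell in 22 of 34 (26 adjusted over the list alone), with Slc27a1, a fatty acid transporter, at -0.82 ± 0.10 and Cpt2 at -0.48 ± 0.07. The median was -0.48, within chips -0.58 to -0.29 and with the chip as a block -0.47. Tricarboxylic acid cycle genes fell in 12 of 22 and rose in 1 (15 and 1 adjusted over the list alone). The median was -0.31, within chips -0.48 to -0.23 and with the chip as a block -0.32. Oxidative phosphorylation genes fell in 15 of 72 (19 adjusted over the list alone), with Cox7b at -0.49 ± 0.08. The median was -0.17, within chips -0.30 to -0.11 and with the chip as a block -0.18. These 8 lists also passed with an estimated correlation, with adjusted p between 0.00235 and 0.0152. With replicate 11 also left out it lay between 0.00462 and 0.0479 (oxidative phosphorylation), the highest of 9 camera alternatives for each list.

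Another 10 lists passed with the preset correlation only, and each is given with its adjusted p under an estimated one. Without replicate 11, STAT3 (adjusted p = 0.043) and cytokine genes (adjusted p = 0.0411) passed with an estimated one too. Calcium handling genes fell in 5 of 18 and rose in 2, also adjusted over the list alone (median -0.23, p = 0.0571). Ion channel genes fell in 7 of 24, also adjusted over the list alone (median -0.20, p = 0.0878), with Kcnd2 at -1.43 ± 0.24. Cytokines and chemokines rose in 10 of 26 and fell in 1 (11 and 1 adjusted over the list alone; median 0.28, p = 0.0569), with Il15 at -1.10 ± 0.12. STAT3 and interleukin 6 family genes rose in 5 of 20 and fell in 2 (9 and 2 adjusted over the list alone; median 0.35, p = 0.0569), with Socs3, an inhibitor of that pathway, at 1.40 ± 0.22. Prostanoid synthesis and receptor genes rose in 3 of 14, also adjusted over the list alone (median 0.13, p = 0.134): Ptgis, the prostacyclin synthase (1.08 ± 0.11), Tbxas1, the thromboxane synthase (0.79 ± 0.12), and Ptgds, a prostaglandin D synthase (0.40 ± 0.10). Endoplasmic reticulum stress genes rose in 6 of 19 and fell in 1 (8 and 1 adjusted over the list alone; median 0.24, p = 0.266), with Asns, the asparagine synthetase, at 1.26 ± 0.15. Cell cycle genes rose in 5 of 29, also adjusted over the list alone (median 0.19, p = 0.52). Ribosomal protein genes rose in 17 of 45 (19 adjusted over the list alone; median 0.14, p = 0.0573), but with median scaling the list's median was -0.02 and its adjusted p 0.627. Circadian genes fell in 2 of 16 (6 adjusted over the list alone; median -0.18, p = 0.173; 0.123 with the preset correlation without replicate 11), and erythrocyte markers in 1 of 10 (none adjusted over the list alone; median -0.21, p = 0.197), that member being Alas2, of haem synthesis, at -1.08 ± 0.35. The lowest adjusted p of 9 camera alternatives for these 10 lists in the order given was 0.000631, 0.000219, 3.45e-05, 5.81e-05, 0.0331, 0.00394, 0.00551, 1.67e-06, 0.0355 and 0.000291. The highest was 0.107, 0.0878, 0.0569, 0.0569, 0.136, 0.3, 0.521, 0.627, 0.3 and 0.3. Their within-chip medians spanned -0.42 to -0.06, -0.37 to -0.13, 0.07 to 0.53, 0.03 to 0.53, 0.08 to 0.31, 0.05 to 0.37, 0.03 to 0.30, 0.09 to 0.20, -0.39 to -0.03 and -0.48 to -0.07.

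In all, 3661 probes were called in KO high EF against WT, 2160 higher and 1501 lower, with 183 higher and 66 lower by at least 2-fold and 260 without a usable gene name. Of the called probes 92.9% had 1 sign within all 4 chips, against 32.2% of all kept probes. Calling on the same arrays favours this. The chip as a block gave 3418 calls, and leaving out replicate 11 gave 4776 (2370 higher and 2406 lower), with 3257 called both ways. With median scaling 983 were higher and 727 lower, and without replicate 11 as well 2289 and 744, so the balance of directions is not settled. Of the further probes of named genes, 12 passed in the named direction. Those of Rcan1 (0.00 ± 0.13 and 0.09 ± 0.66), Ttll1 (0.03 ± 0.08), Comp (1.12 ± 0.42) and Dcakd (-0.23 ± 0.12) did not pass, and a Nmrk2 probe measured -0.42 ± 0.07. Without replicate 11 the second of the Rcan1 probes passed at 1.11 ± 0.12.

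**Figure D2:**
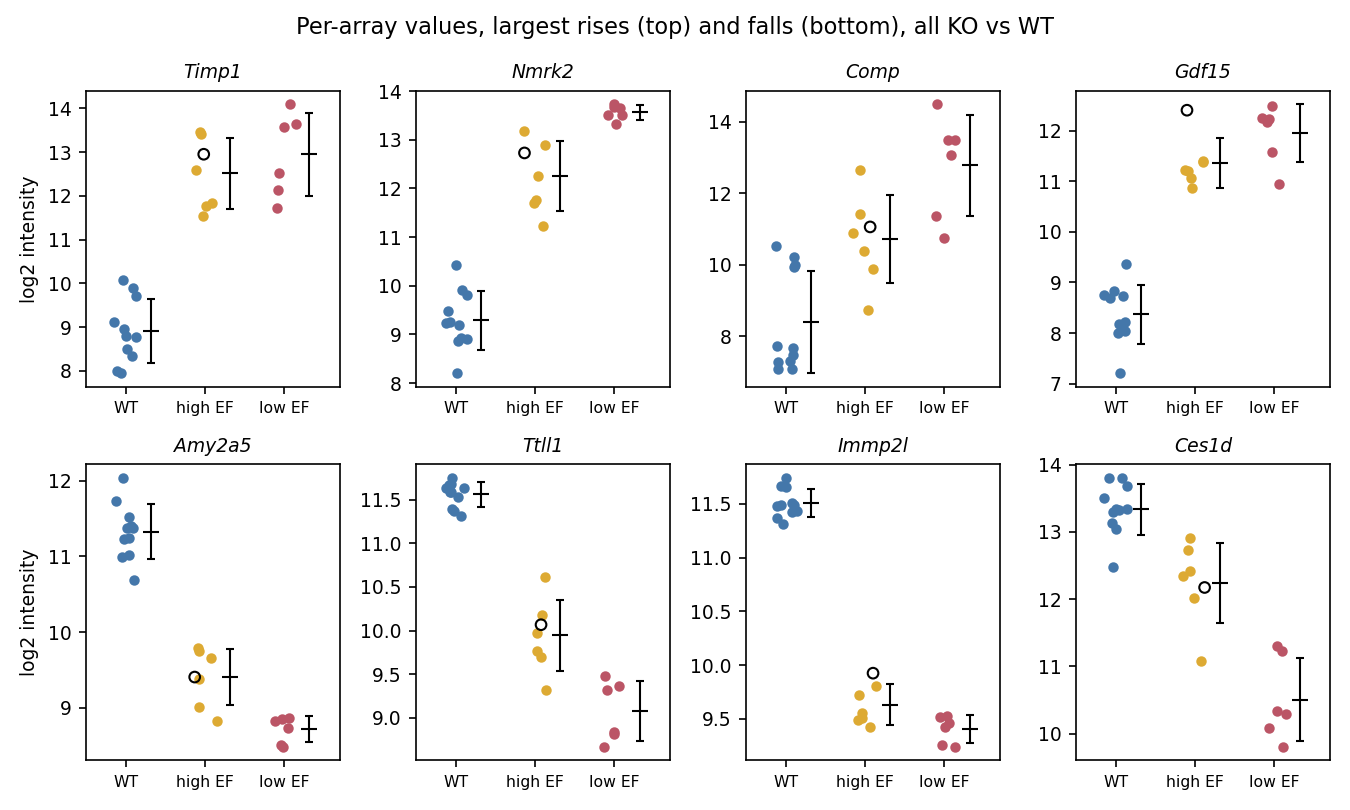
Normalized log2 values of 8 genes, with 1 point per heart, bars at the mean ± SD of each group and an open circle for KO high EF replicate 11. Of the 4 genes with the largest rises over all KO hearts, every KO heart lies above every WT heart for Timp1, Nmrk2 and Gdf15 but not for Comp, and of the 4 with the largest falls on the probe with the smallest p every KO heart lies below every WT heart for Amy2a5, Ttll1 and Immp2l but not for Ces1d.

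The changes of the 2 KO groups against WT were alike. Across probes, the 2 sets of log2 changes had r = 0.743, while simulated unchanged groups that share the controls had a mean r of 0.37 and at most 0.4. The simulation drew each probe independently, so 0.4 is no upper bound for real arrays, whose probes vary together. With the controls split so that no control is shared, the mean r was 0.674, from 0.629 to 0.708 over 20 splits, and without KO high EF replicate 11 it was 0.908; probes are not independent replicates. Higher in both were 1864 probes and lower in both 1304, and no probe called in both groups moved in opposite directions. With the controls split, a test added later, a median of 1300 were higher in both, where independent lists would share 155, and 868 lower in both, where they would share 102. A median of 0 then moved in opposite directions, with 10 as the highest of 20 splits. Of the probes called in either group, 85.4% changed less in KO high EF hearts. In a test added after this was seen, 100 assignments of the KO hearts to groups of 6 and 7, the real one included, gave as large a share 3 times (median of the others 51.6%, highest 88.9%). The slope of KO high EF on KO low EF changes was 0.612 over all probes, against a median of 0.769 in the other assignments. A slope as low came from 11 of the 100. Without replicate 11 the share was 89.2% and the slope 0.626, which no other assignment reached (highest share 86.7%, lowest slope 0.687).

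**Figure D3:**
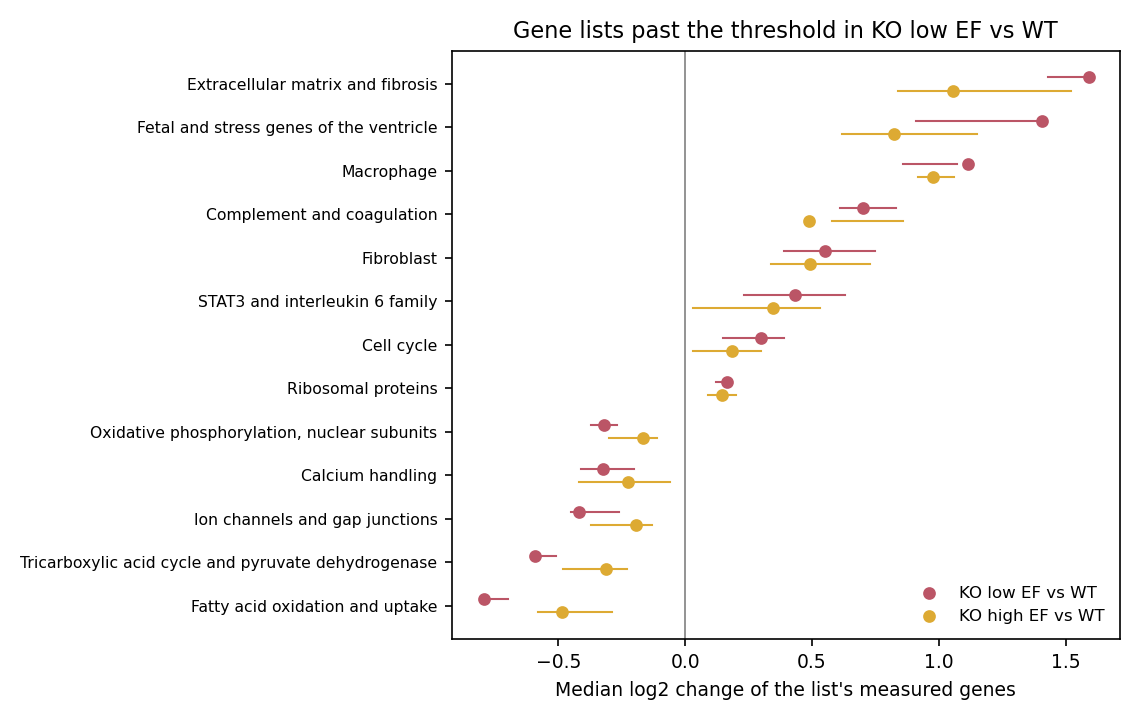
Median log2 change against WT of the 13 gene lists past the threshold in KO low EF hearts, with dots for KO low EF and KO high EF hearts and lines from the lowest to the highest median within single chips, which need not include the dot. Matrix genes lie highest (1.59 and 1.06) and fatty acid oxidation genes lowest (-0.79 and -0.48). The medians of KO high EF hearts lie closer to 0 in each of the 13 lists shown, which choosing the lists by KO low EF hearts favours. Among lists past the threshold only in KO high EF hearts, circadian and erythrocyte medians were farther from 0 there than in KO low EF hearts. Cytokine, prostanoid and endoplasmic reticulum stress medians were closer. With median scaling the median of ribosomal protein genes was -0.02 in KO high EF hearts.

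The comparison of KO low EF with KO high EF asks what goes with the lower EF among knockout hearts. Comp was 3.63-fold higher in KO low EF hearts (1.86 ± 0.49, 6 against 7 hearts), Ecrg4 3.22-fold (1.69 ± 0.46), Col8a2, a collagen, with a log2 difference of 1.38 ± 0.28, Fam180a 2.53-fold and Nmrk2 2.49-fold (1.31 ± 0.30). Sfrp1, an inhibitor of Wnt signalling, was 2.33-fold higher (1.22 ± 0.31), Nrip3 2.30-fold, Lgals3 2.18-fold, and Ddah1, which degrades asymmetric dimethylarginine, 2.18-fold (1.13 ± 0.17). Nrip3 (mean 7.01) and Fam180a (mean 7.29) lay near the array median in KO high EF hearts, so their folds may be too small. Ces1d was 3.32-fold lower (-1.73 ± 0.27), Inmt, an N-methyltransferase, 2.95-fold lower (-1.56 ± 0.38), Ccl11, or eotaxin, 2.90-fold lower (-1.54 ± 0.28), Ky 2.22-fold lower and Cmss1 2.19-fold lower (-1.13 ± 0.14). Scn4b, a sodium channel beta subunit, was 2.16-fold lower (-1.11 ± 0.25), Tmprss13, a serine protease, 2.05-fold lower, P2ry1, a purinergic receptor, 2.00-fold lower and Acot1 1.97-fold lower (-0.98 ± 0.19; -1.17 ± 0.26 on its other kept probe). Adjusted p over the 20 genes taken by the rule ran from 0.000267 (Cmss1) to 0.0475 (Ecrg4).

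Of the genes fixed beforehand, Col1a1 was higher in KO low EF hearts (0.58 ± 0.16, adjusted p = 0.0422). Myh7 (1.03 ± 0.31, adjusted p = 0.069), Pln (-0.37 ± 0.10, adjusted p = 0.0551) and Ccn2 (0.68 ± 0.22, adjusted p = 0.104) did not pass. Neither did Col3a1 (0.82 ± 0.50, adjusted p = 0.488), Postn (0.35 ± 0.16, adjusted p = 0.306) or Timp1 (0.44 ± 0.42, adjusted p = 0.661). Without KO high EF replicate 11, Col3a1 measured 0.18 ± 0.18. Nppa (-0.02 ± 0.26), Nppb (0.12 ± 0.20), Acta1 (0.14 ± 0.23), Ankrd1 (0.11 ± 0.08) and Atp2a2 (0.08 ± 0.05) lay near the top of the scale in both KO groups (means from 15.69 to 15.99). Their values therefore decide nothing about a difference. Ccn2 lay near the top in KO low EF hearts (mean 15.74), so its difference may be too small. Pln passed without KO high EF replicate 11 (adjusted p = 0.0317, with a range of 0.0145 to 1 over 41 alternatives). Myh6 measured -0.03 ± 0.05 on its bright probe, also near the top, and was lower by its less bright probe (-0.59 ± 0.12, adjusted p = 0.00855).

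Matrix genes were higher in 9 of 47 (25 adjusted over the list alone), with Fbn1 at 0.70 ± 0.13 and Bgn at 0.72 ± 0.14. The median was 0.52, within chips 0.16 to 0.60 and with the chip as a block 0.47, and the adjusted p with an estimated correlation was 0.0108. Fatty acid oxidation genes were lower in 18 of 34 (20 adjusted over the list alone), with Plin5 at -0.59 ± 0.08 and Acaa2 at -0.81 ± 0.13. The median was -0.36, within chips -0.41 to -0.19 and with the chip as a block -0.35, and the adjusted p with an estimated correlation was 0.0067. Tricarboxylic acid cycle genes were lower in 8 of 22 (13 adjusted over the list alone). The median was -0.29, within chips -0.38 to -0.02 and with the chip as a block -0.23, and the adjusted p with an estimated correlation was 0.0067. Oxidative phosphorylation genes were lower in 10 of 72 (16 adjusted over the list alone). The median was -0.17, with a mean of only -0.005, within chips -0.15 to -0.04 and with the chip as a block -0.14, and the adjusted p with an estimated correlation was 0.0108. Ion channel genes were lower in 5 of 24 (6 adjusted over the list alone), with Kcnj3 at -0.60 ± 0.11 and Kcnip2 at -0.64 ± 0.15. The median was -0.22, within chips -0.19 to -0.07 and with the chip as a block -0.17, and the adjusted p with an estimated correlation was 0.0347. Fetal and stress genes (2 of 18 higher, 6 adjusted over the list alone, median 0.35), cell cycle genes (none of 29 past the threshold either way, median 0.16) and fibroblast markers (2 of 20 higher, 4 adjusted over the list alone, median 0.14) passed only with the preset correlation. Their adjusted p was 0.126, 0.664 and 0.57 with an estimated one, and 0.219, 0.733 and 0.52 with replicate 11 also left out. The lowest of 9 camera alternatives were 1.54e-05, 0.00626 and 0.00825. Within chips these medians ran from 0.11 to 0.33, 0.04 to 0.42 and -0.11 to 0.26, and with the chip as a block the fibroblast list had an adjusted p of 0.0937. Calcium handling (median -0.08, adjusted p = 0.0276, range 0.00304 to 0.369) and mesothelium genes (median 0.16, adjusted p = 0.0219, range 0.0206 to 0.126) passed with that block. Each also passed in 2 of the 8 other camera alternatives, but not in the main test. Macrophage markers did not pass (1 of 22 higher, also adjusted over the list alone, median 0.09, adjusted p = 0.23, within chips 0.00 to 0.01, chip-blocked 0.04).

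Between the KO groups limma called 743 probes, 237 higher and 506 lower in KO low EF hearts, with 18 higher and 14 lower by at least 2-fold and 52 without a usable gene name. The count fell to 213 with the chip as a block and to 18 with median scaling (12 higher and 6 lower), and was 1078 without KO high EF replicate 11 (465 higher and 613 lower), with 677 called both ways. Chip 4 held 3 of the 7 KO high EF hearts, those with the highest EF, and no KO low EF heart. With the block, a chip effect and lost information therefore cannot be told apart. Leaving out single arrays gave 395, 372 and 394 without KO low EF replicates 1, 2 and 3, 430 without KO high EF replicate 13 and 1115 without KO high EF replicate 8, and between these values for each other array. Of the called probes 77% had 1 sign within the 3 chips holding both groups, against 25.6% of all kept probes. Calling on the same arrays favours this too. With the chip as a block 11 of the 21 named genes past the threshold still passed. Those that did not included Col1a1, Comp, Ecrg4, Fam180a, Nmrk2, Sfrp1, Lgals3, Inmt and Ky, with adjusted p from 0.0621 (Ky) to 0.166 (Ecrg4). With the block the differences stayed near those above for Comp (1.94 ± 0.54), Col1a1 (0.58 ± 0.17), Nmrk2 (1.31 ± 0.34), Ecrg4 (1.58 ± 0.51), Lgals3 (1.11 ± 0.31) and Inmt (-1.52 ± 0.43), with slightly larger standard errors, and that of Ky shrank to -0.95 ± 0.24. Over all alternatives the adjusted p of Ky spanned 0.000437 to 0.361 and that of Ecrg4 0.00373 to 0.166, and Col1a1 passed in 20 of 41 and Ecrg4 in 17 of 40. Within chip 2, Sfrp1 measured -0.88 and Scn4b 0.32, against their overall directions. Of the further probes of named genes, 4 passed in the named direction and none against it. Those of Comp (2.06 ± 0.71), Nmrk2 (2.08 ± 0.59 and -0.20 ± 0.08), Sfrp1, Inmt (-1.13 ± 0.68), Ccl11 (-0.48 ± 0.26), Scn4b (-0.37 ± 0.14) and Col8a2 (0.15 ± 0.11) did not pass. Without KO high EF replicate 11, the first of the Nmrk2 probes (1.37 ± 0.30) and those of Sfrp1 (0.87 ± 0.22), Inmt (-1.87 ± 0.43) and Ccl11 (-0.72 ± 0.21) passed.

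Over all KO hearts against WT, Timp1 rose 14.1-fold (3.81 ± 0.31, 13 against 11 hearts), Nmrk2 12.2-fold (3.61 ± 0.22), Gdf15 9.71-fold, Mfap5 7.04-fold, Mfap4 6.46-fold, Rcan1 5.21-fold and Tnc, from WT values near the array median, 5.12-fold, which may be too small, and for each of these genes every KO heart lay above every WT heart. Comp (3.36 ± 0.53, and 2.05 ± 0.36 on its other kept probe) and Lgals3 (2.54 ± 0.22) rose with some overlap. Because of KO high EF replicate 11, the rule could again not take Lox or Serpina3n. Amy2a5 (4.81-fold lower, -2.27 ± 0.13), Ttll1 (4.14-fold lower), Immp2l (3.96-fold lower) and Kcnv2 (3.83-fold lower) lay below every WT heart in every KO heart. The other kept Amy2a5 probe measured only -0.62 ± 0.12. Ces1d (3.91-fold lower), Fbp2 (3.84-fold lower), Acot1 (3.53-fold lower, and -2.27 ± 0.19 on its other kept probe), Slc40a1 (3.36-fold lower) and Fah (3.29-fold lower) fell with overlap. Of the further probes of named genes, 13 passed in the named direction. Those of Rcan1 (0.02 ± 0.11 and 0.81 ± 0.56, the latter 1.32 ± 0.10 and past the threshold without KO high EF replicate 11) and Ttll1 (0.04 ± 0.07) did not, and a Nmrk2 probe fell by 0.52 ± 0.06. Complete separation of this kind held for 728 of the 25425 kept probes, where chance alone would give 0.0204 probes.

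The genes fixed beforehand moved over all KO hearts as in the KO groups: Nppa (1.26 ± 0.19), Nppb (1.26 ± 0.15), Myh7 (1.46 ± 0.23), Acta1 (0.93 ± 0.17), Col1a1 (2.04 ± 0.12), Col3a1 (1.72 ± 0.37), Postn (0.71 ± 0.12), Ccn2 (2.09 ± 0.16) and Ankrd1 (0.37 ± 0.06) rose and Pln fell by 0.53 ± 0.08. Myh6 fell by 0.71 ± 0.09 and Atp2a2 by 0.36 ± 0.06 on their less bright probes, with -0.02 ± 0.04 (adjusted p = 0.728) and 0.01 ± 0.04 (adjusted p = 0.931) on the named ones. Limma called 6460 probes, 3342 higher and 3118 lower, and 293 and 139 of them by at least 2-fold. With median scaling 2734 were higher and 1766 lower, and without KO high EF replicate 11 as well 4705 and 2152. The count was 5986 with the chip as a block and 8569 without KO high EF replicate 11, with 6413 called both ways, and all 30 named genes past the threshold kept their sign within each chip and passed with the chip as a block. Of the 14 lists past the threshold, cell cycle (adjusted p = 0.368) and cytokines and chemokines (adjusted p = 0.0948) lost it with an estimated correlation, ribosomal proteins with median scaling (median 0.04, adjusted p = 0.369), and cytokines also with the chip as a block (adjusted p = 0.0506). With an estimated correlation and without replicate 11, calcium handling (adjusted p = 0.0843), STAT3 (adjusted p = 0.0774) and ribosomal protein genes (adjusted p = 0.102) lost it too, and cell cycle and cytokine genes had 0.401 and 0.102. The lowest of 9 camera alternatives were 0.000863, 0.00238 and 1.24e-06 for cell cycle, cytokine and ribosomal genes, and 0.000436 and 0.000719 for calcium handling and STAT3 genes.

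Within the 13 KO hearts, expression was fitted on EF as a continuous measure, which overlaps with the split into groups by EF. Ces1d rose with EF by 0.51 ± 0.07 log2 units per 10 points, Cyp2b10, a cytochrome P450, by 0.51 ± 0.09, Ccl11 by 0.42 ± 0.10 and Ky by 0.34 ± 0.07. Among the lowest slopes were those of Ecrg4 (-0.53 ± 0.09), Fam180a (-0.42 ± 0.09), Col8a2 (-0.42 ± 0.08) and Nmrk2 (-0.39 ± 0.07). Adjusted p over the 10 genes taken by the rule ran from 0.00757 (Ces1d) to 0.0393 (Ccl11). Limma called 507 probes, 339 rising and 168 falling with EF, and 1415 without KO high EF replicate 11. With the chip as a block none passed (3461 had an unadjusted p under 0.05 without the block), and 556 did with the block and without replicate 11. Median scaling also left none. Chip 4 held the 3 KO hearts with the highest EF (60.2, 60.8 and 76.4%) and no KO low EF heart. The chip block thus also takes out part of the EF range, so a chip effect and lost information cannot be told apart. Without KO low EF replicates 1 to 5 the count was 154, 101, 238, 283 and 261 in turn, and without KO high EF replicates 10, 11 and 12 it was 311, 1421 and 238. With the chip as a block the adjusted p of the 10 genes ran from 0.132 (Ces1d, Ecrg4 and Nmrk2) to 0.394 (Ccl11), the highest of 27 alternatives for each of these 4 genes, whose lowest were 0.000226, 0.000593, 0.000433 and 0.00554. With the block their slopes were 0.62 ± 0.09 (Ces1d), -0.65 ± 0.11 (Ecrg4), -0.46 ± 0.08 (Nmrk2) and 0.46 ± 0.15 (Ccl11), larger than without it, as were their standard errors. Those of Cyp2b10 (0.40 ± 0.13) and Col8a2 (-0.38 ± 0.11) were smaller.

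Within the 11 WT hearts, where EF spanned 71.4 to 86.1%, limma called no probe (2343 had an unadjusted p under 0.05). All WT mice aged 33 weeks had a lower EF (71.4 to 81%) than the younger ones (82.1 to 86.1%). The WT slopes, and their difference from the KO slopes, therefore cannot be told apart from age. The 5 genes with the smallest p included H2-Ab1, an MHC class II chain (-1.01 ± 0.16 per 10 points), Urah (0.77 ± 0.13), Egf, the epidermal growth factor (0.84 ± 0.14), and Lgals3bp (-0.78 ± 0.14), each with an adjusted p of 0.166. With the chip as a block 14 probes passed, among them H2-Ab1 (adjusted p = 0.0488, 0.0244 to 0.814 over 25 alternatives) and Egf (adjusted p = 0.0211, 0.0211 to 0.814). Without WT replicate 7 there were 2 calls and without WT replicate 11 there was 1. Simulated slopes of 0.5 per 10 points were recovered for 25.4% of probes within WT, against 100% within KO. The difference of the slopes between KO and WT passed for no probe by limma (1402 with an unadjusted p under 0.05), and for 2 without KO high EF replicate 11.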

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

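Of the tests in this part, those of a local defect, of lower overall signal, of a transgene, of low EF as the source of the 4 probes, of 1 deviating array and of reassigned KO hearts were chosen only after the result was seen. In the KO groups, 15 of 122 tests found 1 array with a gap to its nearest neighbour too large a share of the group's range, where chance alone gives about 6. In KO low EF hearts these were Acta1 (share 0.759; 15.34 in replicate 1 against 15.82 to 15.97) and Acot1 (0.805; 8.09 in replicate 2 against 7.62 to 7.71). In KO high EF hearts, apart from replicate 11, they were Nppa (0.597; 15.9 in replicate 8 against 15.95 to 15.99) and Egf (0.651; 8.57 in replicate 13 against 7.74 to 8.03).

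The other 11 were all KO high EF replicate 11, 10 of them genes. It was lower than the rest of its group for Col3a1 (share 0.753), Ankrd1 (0.656), Lox (0.705), Serpina3n (0.867), Fbp2 (0.852), Fah (0.728), Slc40a1 (0.733), Dcakd (0.963) and Lgals3bp (0.928), and higher for Gdf15 (0.657). Its median correlation with the other arrays stood apart too (0.966 of the range).

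On this array 1777 probes lay over 2 log2 units below their group's median and 11 above, against at most 44 on another array. Different RNA is argued against, since 2 probes of a gene deviated together with r of only 0.051 (95% interval 0.025 to 0.077, across 5726 genes, which are not independent replicates), where the other arrays had 0.073 to 0.46. A lower overall signal would have left bright probes in place after normalization, but 16.2% of them were over 2 log2 units low, against at most 0.57% elsewhere. A local defect of the array or its hybridization stays open: WT replicate 1, at 1 neighbouring position of the chip, shared its deviations with r = 0.133, above the 0.061 of any array not next to it. But KO high EF replicate 12, at the other neighbouring position, had only 0.007. The larger r is small, and no biological explanation beyond different RNA was tested.

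Among probes without a platform symbol, 4 probes chosen after their values were seen, which the authors name IGHV1S120, LOC382696, IGHV1S13 and IGHV1S35, were near the floor in every WT heart (at most 6.81). Their mean was higher by 2.77 ± 0.21 in KO low EF and by 3.17 ± 0.20 in KO high EF hearts, and with WT near the floor these differences may be too small. B lymphocytes or plasma cells are argued against, since none of 7 measured B lymphocyte markers was called 2-fold higher and their median was -0.147 in KO low EF hearts, and low EF as the source is argued against too, since without KO high EF replicate 11 KO low EF minus KO high EF was -0.675 ± 0.125 (adjusted p = 0.00299). The first evaluation of low EF, with all arrays, gave -0.40 ± 0.23 for the mean and decided nothing. Replicate 11 was left out after that. With all arrays LOC382696 gave -0.63 ± 0.15 (adjusted p = 0.0209) and IGHV1S35 -0.71 ± 0.13 (adjusted p = 0.00345). IGHV1S120 (-0.12 ± 0.42) and IGHV1S13 (-0.14 ± 0.42), near the floor on replicate 11, did not pass. A transcript from a cardiomyocyte promoter carried by the KO mice, such as a recombinase under Myh6, stays open after 3 evaluations: the first, with all 13 KO arrays, would have excluded it because 2 of the 4 probes overlapped WT, but that condition was wrong, as only replicate 11, at 6.01, overlapped and the lowest other KO value was 8.56. The second, over the 12 other KO arrays, gave r = 0.462 with the brighter Myh6 probe (permutation p = 0.131; rho 0.352, permutation p = 0.263; r 0.142 without the 2 farthest arrays), which decides nothing, since that probe is saturated (15.83 to 16.02). The third, added after these, gave r = 0.823 with the less bright probe (permutation p = 0.00126; rho 0.741, permutation p = 0.00757; r 0.731 without the 2 farthest arrays), a value 1.46% of kept probes reach, but r was 0.806 within KO low EF and -0.063 within KO high EF hearts (6 arrays each; rho 0.771 and 0.257).

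Changes in KO high EF hearts lay between WT and KO low EF hearts, with a slope of 0.612 on KO low EF changes. Of 100 assignments of the KO hearts to groups, 11 reached it, and the median of the others was 0.769. Without replicate 11 the slope was 0.626, which only the real assignment reached, with a median of 0.912 for the others. A smaller share of cardiomyocyte RNA as the whole source is argued against, because sarcomere genes exceeded fatty acid oxidation genes by 0.828 ± 0.126 in mean change. Among members below 14 on the log2 scale (8 and 24) the difference was 0.943 ± 0.242. Fibroblast markers also exceeded endothelial ones by 0.772 ± 0.197, and macrophage markers exceeded endothelial ones by 1.125 ± 0.124. These standard errors are over list members, which are not independent replicates, and leave out the spread between hearts. The deviating array is argued against too, since the slope of KO high EF on KO low EF changes was only 1.021 times as large without replicate 11. With the chip as a block that slope was 1.123 times as large, a move towards equal changes. Uneven chips as part of the source therefore stay open. A graded response of the heart stays a hypothesis, and because the KO groups were formed by EF, the data cannot say whether EF or the expression came first.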

How the results depend on the processing

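Some settings were chosen after seeing the data: leaving out KO high EF replicate 11 (alone, with WT replicate 1, with median scaling, with the chip as a block or with an estimated correlation), keeping probes above the median in every other array, and, for lists, less bright probes and median scaling. The other settings here were chosen beforehand. Over all settings, named genes gave 5868 values with the same direction and side of the threshold, 267 weaker, 28 stronger, 129 moved and 2 reversed, and lists 1480 the same, 56 weaker and 64 stronger. The 2 reversed values lay within chip 2: Sfrp1, KO low EF vs KO high EF, at -0.883 and Scn4b, KO low EF vs KO high EF, at 0.32. Of genes not past the threshold, 25 values changed direction. Unless a reason is given, the cause was not tested.

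With scaling to a common median, calls fell to 1710 for KO high EF against WT, 18 between the KO groups and 0 for EF within KO, while without replicate 11 scaling gave 186 between the KO groups. With the chip as a fixed block there were 213 calls between the KO groups, 0 for EF within KO and 14 for EF within WT, and 11 for EF within WT with replicate 11 also left out. Age as a covariate gave 795 for EF within KO. Array weights gave 1977 between the KO groups, 1942 for EF within KO and 9 for EF within WT, and robust and trended variance gave 2 for EF within WT. Testing for at least 1.5-fold asks for larger changes and gave 2266 (KO low EF against WT), 964 (KO high EF against WT), 239 (between KO groups), 1585 (all KO) and 139 (EF within KO). Fitting only the groups compared, with fewer arrays, gave 107 between the KO groups. Without replicate 11, EF within KO had 1415 calls, and without it and WT replicate 1 there were 1417, with 1318 between the KO groups.

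The replicate numbers do not pair the hearts by the check set for it: same-numbered WT and KO arrays had a mean correlation of deviations of 0.057, and 2 of 11 WT arrays correlated best with their own number. The planned replicate block, which therefore carries no pairing, gave 5242 calls for KO low EF against WT, 1532 for KO high EF against WT, 2 between the KO groups and 5863 for all KO.

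Lists past the threshold fell to 8 (KO high EF against WT) and 5 (between KO groups) with an estimated correlation, and with replicate 11 also left out to 8 (KO low EF against WT), 10, 5 and 9 (all KO) in the 4 comparisons. Fry, which does not compare a list with other genes, gave 23 (KO low EF against WT) and 26 (all KO) by direction, and 33, 30, 15 and 33 for changes either way in the 4 comparisons. The agreement of the 2 KO groups was 0.674 with the controls split and 0.908 without replicate 11. Leaving out each array gave 5599 to 8503 (KO low EF against WT), 3197 to 4768 (KO high EF against WT), 372 to 1115 (between KO groups), 6058 to 8565 (all KO), 101 to 1421 (EF within KO) and 0 to 2 (EF within WT). Probes near the array median of 6.77 and at the top of the scale carry little signal over background or are compressed, which limits their changes.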

Other observations

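No test in this part was chosen after its result was seen. Other lists did not pass as a whole in KO low EF against WT but held members that did. In the prostanoid list (3 of 14 higher, 1 lower; median 0.15, adjusted p = 0.119) Ptgis, the prostacyclin synthase, rose by 1.68 ± 0.12. Adrenergic and cyclic AMP genes went both ways (5 of 28 higher, 10 lower; median -0.09, adjusted p = 0.242), with the receptor Adra1a at -1.03 ± 0.10 and the receptor kinase Grk5 at 1.08 ± 0.15. In the renin-angiotensin and natriuretic peptide list (2 of 14 higher, 4 lower; median -0.13, adjusted p = 0.282) Ace, which forms angiotensin II, rose by 1.81 ± 0.13 and the receptor Agtr1a was at -1.01 ± 0.14. Glucose genes were split (6 of 20 higher, 7 lower; median 0.03, adjusted p = 0.825), with Pfkp at 1.38 ± 0.12 and the transporter Slc2a4 at -0.94 ± 0.09. Antioxidant genes (7 of 31 higher, 9 lower; median 0.02, adjusted p = 0.98) included Nox4 at 1.94 ± 0.23 and Gpx3 at 1.37 ± 0.16. Cytokines and chemokines (8 of 26 higher, 3 lower; median 0.42, adjusted p = 0.0733) included Il15 at -1.93 ± 0.12 and Cx3cl1 at 1.05 ± 0.12. Endoplasmic reticulum stress (median 0.27, adjusted p = 0.228), heat shock (0.11, 0.368), apoptosis (0.16, 0.128), proteasome and atrophy ligases (0.03, 0.896), interferon response (0.27, 0.114), circadian clock (-0.10, 0.431) and immediate early genes (0.24, 0.148) did not pass. The member with the smallest or next smallest p in each, in that order, was Asns at 1.31 ± 0.16, Hspb1 at 1.01 ± 0.16, Gadd45g at 1.49 ± 0.18, Trim63 at -0.68 ± 0.06, Ifit3 at 0.91 ± 0.22, Nr1d2 at -0.76 ± 0.14 and Egr2 at 1.48 ± 0.27.

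Markers of other cells did not pass in KO low EF against WT for endothelium (median -0.01, adjusted p = 0.896), smooth muscle and pericytes (0.07, 0.777), T lymphocytes (0.05, 0.98), B lymphocytes (-0.15, 0.547), neutrophils (0.05, 0.886), mast cells (-0.09, 0.98), atrial cardiomyocytes (-0.22, 0.98), erythrocytes (-0.17, 0.244), adipocytes (0.02, 0.886), skeletal muscle (0.18, 0.547), Schwann cells and neurons (0.03, 0.98) and mesothelium (0.26, 0.064). Single members did, both ways: Acta2 of smooth muscle rose by 1.01 ± 0.18, Pmp22 of Schwann cells by 1.26 ± 0.09, Krt18 of mesothelium by 2.29 ± 0.20 and Scd1 of adipocytes by 0.95 ± 0.10. In the same lists Smtn of smooth muscle was at -0.52 ± 0.12, Mbp of Schwann cells at -0.43 ± 0.13 and Thrsp of adipocytes at -0.86 ± 0.15. Of 12 atrial genes 4 rose, such as Clu (0.81 ± 0.09), and 3 fell, such as Stard10 (-1.41 ± 0.15). The list of sex genes did not pass (adjusted p = 0.263), though Ddx3y was at -0.35 ± 0.09. The test's direction differed from the sign of the median or mean for glucose, proteasome, endothelium, atrial and Schwann lists in KO low EF against WT, and for sarcomere, T, B, neutrophil and adipocyte lists in KO high EF against WT. It also differed for immediate early and T lists between the KO groups, and for sarcomere, glucose, mast, smooth muscle and adipocyte lists over all KO hearts.

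For each group comparison, 1 of 100 splits of the arrays, the real one, gave as many calls, which makes chance alone unlikely. With 100 splits no share below 1 in 100 can be reached. The highest other split had 1 call against 6205 (KO low EF against WT), 1560 against 3661 (KO high EF against WT, a split that keeps 16 of 18 arrays in their real group), 2 against 743 (between KO groups) and 1 against 6460 (all KO). For EF within KO the highest other had 0 against 507 in 1 of 100 reassignments as large. These numbers concern the main fit. With the chip as a block there were 213 calls between the KO groups and 0 for EF within KO, and with median scaling 18 and 0. For EF within WT the real count was 0 (limma; 2343 at an unadjusted p under 0.05), so all 100 reassignments had to reach it and their number says nothing about chance. The highest gave 163.

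Immp2l, a largest fall chosen by rule, had the smallest adjusted p over all KO hearts among named genes (7.25e-17), with 11.31 to 11.74 in WT and 9.24 to 9.92 in KO hearts, and differed little between the KO groups (-0.23 ± 0.09, adjusted p = 0.194).

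DNA of another strain flanking the targeted gene may make neighbours of Ptger4 change alike in both KO groups. Of 111 tested neighbours 10 changed so (Abra, Dab2, Dap, Cmbl, Sybu, Npr3, Prlr, C7, Angpt1 and Baalc), against 491 of 13668 other genes, an odds ratio of 2.66 (95% interval 1.23 to 5.13, Fisher exact p = 0.00715). Neighbours can also change with the heart's state, as Npr3 and Angpt1 belong to lists fixed beforehand, so the hypothesis stays undecided.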
